A study of Homo sapiens with 2 samples.

How the data were processed

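The labels describe poly(A) mRNA sequencing of IMR90 lung fibroblasts at passages 7 to 9, transfected with 1.5 µg of control siRNA or of siRNA targeting H1.5 and collected after 48 h. Libraries were made from 5 µg of total RNA with an Illumina mRNA-seq kit, per the labels' protocols. Each group has 1 library, assigned from the transfection label.

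The authors deposited 1 table per library with gene symbols, RefSeq accessions and RPKM values, per the file headers. The submitters' processing notes name TopHat 1.3.2 and genome build hg19. The counting tool, the gene annotation, the treatment of reads with several matches and the use of strand are not given in the sources used here. RPKM divides reads by transcript length and by the library's read total, so the deposited values carry no counts and depend on the gene models that were counted on. Both tables hold the same 23672 rows in the same order. Of these, 28 symbols had been turned into dates by a spreadsheet and were kept apart by accession.

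Read totals were estimated because low RPKM values fall on whole multiples of what 1 read is worth. RPKM times exon length was searched for the total that made most values whole within 0.05 reads, over rows with 1 known transcript length. This gave 65361857 reads for the control and 54416876 for the H1.5 siRNA library. At these totals 56.0% of 3535 and 56.9% of 3453 rows checked were whole. With each row's length changed by a random factor, these were 9.57% and 9.66%. Exon lengths came from GENCODE release 29 on GRCh38 through RefSeq accessions, which placed 22384 rows (94.6%) on 1 chromosome. The submitters' notes name another build, so these serve for lengths and for the spacing of neighbouring genes, and no coordinate was converted. Estimated reads are RPKM times length times total, rounded. They rest on GRCh38 lengths and are estimates. Of 22945 rows whose accession was known, 95.3% carried a symbol matching it.

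Values were compared as log2((H1.5 siRNA RPKM + 1)/(control RPKM + 1)), with 1 row per symbol, the one with the highest mean, among rows with a mean of at least 1 RPKM. With 1 library per group no test between the conditions was made. The count of rows at least 2-fold apart follows a rule of size. Read ratios have exact conditional binomial 95% intervals, and a test of reads was adjusted by the Benjamini-Hochberg method; both compare the libraries and cover counting error only. A list's median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on level in 20 bins, and stood apart below percentile 2.5 or above 97.5. Lists needed 5 rows. Y-linked genes and XIST were left out.

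The comparison, the lists, the alternatives and the rule for named rows were fixed before the data were examined. That rule takes the linker histone rows, the 12 rows with the highest and the 12 with the lowest log2 ratio, leaving out small RNA rows and rows with fewer than 20 reads, and up to 4 rows per described list with the largest absolute log2 ratio, for gene families among rows with a mean of at least 0.5 RPKM. Rows singled out for a high or an unexpectedly low level were chosen after their values were seen, and results on some items are not reported here. Alternatives were pseudocounts of 0.1, 0.5 and 5 RPKM, 3 scalings, the mean of a symbol's rows, no filter or a mean of at least 5 RPKM, thresholds of 1.5-fold and 3-fold, small RNA rows left out, 10 bins, and the exact test as well. A minimum of 20 estimated reads was chosen after seeing the data.

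Whether row values line up with exons elsewhere on the chromosome was examined in windows of 20 Mb on GRCh38. Protein-coding exons and rows, the rows weighted by their centred log2(mean RPKM + 1), were cross-correlated in bins of 50 bp for displacements up to 3 Mb, leaving out those under 2 kb. Alternate 1 Mb blocks of a window formed separate parts, and a window counted where both parts picked displacements within 1 kb. The same was done with values reassigned at random among the rows of a chromosome, 20 times, and both were repeated under other window, block and floor settings. Windows counted under any setting were then used to look up which coding exons lay under each displaced row, by at least 50 bp.

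The procedures were tested on simulated data. For the comparison of the libraries, Poisson reads were drawn for 2788 rows with 200 rows changed. Of the 100 rows changed 4-fold, 84.0% came out at least 2-fold apart, the pseudocount hiding low rows, and 0 of the unchanged rows did. The exact test called 0.348% of unchanged rows. For the list comparison, rows were drawn at random from shuffled ratios, so linked rows were not simulated. Of 400 unshifted lists 5.25% stood apart, and 20 of 20 lists of 12 rows shifted by 0.50 did. For the displacement scan, with every row read 75 kb away, 22 of 30 windows gave the right displacement and the parts agreed in 8. With rows shuffled over all chromosomes, the parts agreed in 0 of 41 windows. Simulated values had no counting noise and 1 displacement throughout. How the scan does on noisy values or on displacements that differ between regions was therefore not simulated. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.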

Results

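Poly(A)-selected RNA was sequenced from IMR90 cells, human lung fibroblasts, after transfection of a control siRNA or of an siRNA against the linker histone H1.5. The protein is encoded by HIST1H1B and binds the DNA that links nucleosomes. Cells were collected 48 h after transfection. The comparison asked how mRNA levels differ between control and H1.5 knockdown cells, and each group holds 1 library. No difference below therefore has a replicate check, and intervals on reads cover counting error only. Each table lists 23672 rows with a gene symbol and a value in RPKM, which scales reads to transcript length and to the reads mapped in the library. Steps of whole reads in the low values gave 65361857 reads for the control library and 54416876 for the H1.5 siRNA library. The 22384 rows with a known exon length together accounted for 4572940 reads in the control (7.00%) and 3965082 in the H1.5 siRNA library (7.29%).

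The targeted gene could not be followed in these tables. The row of HIST1H1B was listed at 0 RPKM in the control library and at 0 RPKM in the H1.5 siRNA library, so it neither checks the labels nor gives a ratio. Rows of genes that every cell uses were listed at 0 as well, and mRNAs of replication-dependent histones largely lack the poly(A) tail that the kit selects. Of the other linker histone genes, HIST1H1A, HIST1H1C, HIST1H1E, H1FX, H1FNT and HILS1 were also listed at 0 in both libraries. HIST1H1D stood at 0.0985 RPKM in the control and 0.355 with H1.5 siRNA, from an estimated 4 and 13 reads. HIST1H1T, the testis form, stood at 0.401 and 0.279 RPKM, and H1F0, the form of non-dividing cells, at 0.0197 and 0.0315 RPKM. The row of H1FOO, the oocyte form, was the one high linker histone row, with 81.7 RPKM in the control and 91.6 RPKM with H1.5 siRNA. Its read ratio was 1.12 (exact 95% interval 1.08 to 1.16), a comparison of the libraries and not of the conditions.

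The levels did not follow the genes' names. Of 15 genes that fibroblasts or all cells use, looked up after the values were seen, 8 were listed at 0 in both libraries: B2M, VIM, COL1A1, HPRT1, TBP, YWHAZ, RPL3 and RPS6. A further 6 lay between 0 and 1 RPKM. ACTB, the main cytoplasmic actin, had 0.101 RPKM in the control and 0.0710 with H1.5 siRNA, and FN1, fibronectin, had 0.00633 and 0.00761. GAPDH alone among them was above 1, with 6.57 RPKM in the control and 12.1 with H1.5 siRNA. Across the lists of ribosomal protein, housekeeping, matrix and contractile genes, 63 of 178 rows were at 0 in both libraries (35.4%) and 143 had a mean below 1 RPKM (80.3%). Among all 23526 distinct rows, 46.0% were at 0 in both libraries and 87.7% had a mean below 1 RPKM. The highest row was the microRNA row MIR589, with 3911 RPKM in the control and 2259 with H1.5 siRNA. Among rows other than small RNA rows, the highest were LINGO4 with 786 and 945 RPKM, PRDX2 with 431 and 302, GRINA with 313 and 387, and CA9 with 347 and 193. HOXC8 had 189 and 221 RPKM. Gene names below therefore name rows of the table, and no level is read as the expression of the gene of that name.

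Few rows lay far apart between the libraries. Among 2899 rows with a mean of at least 1 RPKM, 44 were at least 2-fold higher with H1.5 siRNA and 57 at least 2-fold lower on the log2(RPKM + 1) scale, 3.48% in all, while 86.6% lay within 1.5-fold. The scale understates the change of low rows. The median log2 ratio was 0.04 with an SD of 0.41 across rows. The libraries correlated across these rows with a Pearson r of 0.951 and a Spearman rho of 0.909, where rows are not independent replicates. An exact conditional binomial test of estimated reads with Benjamini-Hochberg adjustment, which compares the libraries and not the conditions, passed 0.05 for 1722 of 2788 rows (61.8%). These included all 100 rows at least 2-fold apart that had a read estimate.

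On the log2(RPKM + 1) scale the highest ratio belonged to SNX14, a sorting nexin, with 14.6 RPKM in the control and 62.3 with H1.5 siRNA (log2 ratio 2.02). Its read ratio was 4.27 (exact 95% interval 4.11 to 4.44), below those of the lower rows OSBPL2 (20.8, interval 15.05 to 29.50), GRAMD2 (5.78), PKM (5.74) and BIRC2 (4.71). PKM, a pyruvate kinase, stood at 1.59 and 9.13 RPKM (1.97), and GRAMD2 at 1.48 and 8.54 RPKM (1.94). Both lie on chromosome 15 and had nearly equal read numbers, an estimated 318 and 317 in the control, although their annotated exons share 0 bp on GRCh38. OSBPL2, an oxysterol-binding protein gene, had 0.150 and 3.09 RPKM (1.83), from an estimated 39 and 675 reads. ABHD11-AS1 (1.59) and ABHD11 (1.38) share 65 bp of annotated exon on GRCh38. BIRC2, an inhibitor of apoptosis, had a log2 ratio of 1.56, the macrophage receptor gene MARCO 1.47, C17orf104 1.42 and LOC729966 1.41. CDKN1C, which encodes the cell cycle inhibitor p57, stood at 33.3 and 88.2 RPKM (1.38; read ratio 2.65, interval 2.56 to 2.75). MLN, the motilin gene, had a log2 ratio of 1.37.

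On the same scale the lowest ratio belonged to DSTN, which encodes the actin-depolymerising factor destrin, with 43.1 RPKM in the control and 5.57 with H1.5 siRNA (log2 ratio −2.75). Its read ratio was 0.129 (exact 95% interval 0.121 to 0.137). HLA-C, a class I histocompatibility gene, had 7.36 and 1.33 RPKM (−1.84). KLF11 had 4.25 and 0.560 RPKM (−1.75), and GLRX, a glutaredoxin, 7.91 and 1.70 RPKM (−1.72). GEMIN4 (−1.66) and GLOD4 (−1.49) lie on chromosome 17. The row of the connexin gene GJC3 was the most abundant of the 12 lowest, with 90.8 and 30.4 RPKM (−1.55). HNRNPA1 (−1.51) and HNRNPA1P10 (−1.54) are near-identical copies. Whether their rows share reads, or hold reads of these sequences at all, was not tested. C1orf194 had a log2 ratio of −1.50, the protease gene BMP1 −1.48 and the defensin gene DEFB115 −1.48.

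**Figure D1:**
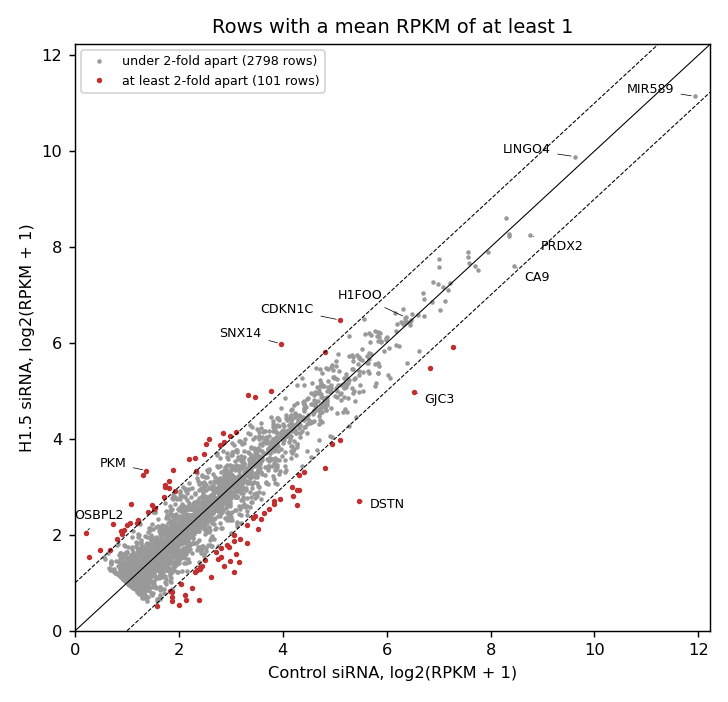
Each point is 1 of 2899 rows with a mean of at least 1 RPKM, placed by log2(RPKM + 1) in the control siRNA library (horizontal) and the H1.5 siRNA library (vertical). The solid line marks equal values and the dashed lines a 2-fold difference on this scale; the 101 rows at least 2-fold apart are red, with DSTN at 43.1 and 5.57 RPKM farthest from the solid line.

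Of 45 gene lists, 26 had at least 5 rows to test, and 5 of them stood apart from random lists matched on level. Chance would give 1.3 if the rows of a list were independent. Rows of a real list can be linked, so the excess over 1.3 cannot be weighed. The list results are statements on rows with those names. Collagen and matrix rows were lower with H1.5 siRNA as a list (12 rows, none 2-fold apart, median log2 ratio −0.20, percentile 1.01). Among them FBN2 (−0.49), COL7A1 (−0.50) and COL15A1 (−0.59) had negative ratios and COL16A1 a positive one (0.62). Ribosomal protein rows lay higher (12 rows, none 2-fold apart, median 0.28, percentile 98.7), with RPL39L at 0.76, RPS26 at 0.75, RPL4 at 0.68 and RPL27A at −0.70. Of the 82 ribosomal protein rows, 37 were at 0 in both libraries.

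Rows of chemokine and interferon gene clusters had the lowest list median (5 rows, 1 at least 2-fold lower, median −0.70, percentile 0.04). CCL15 stood at 154 and 59.4 RPKM (−1.36), CXCL9 at 4.22 and 1.70 (−0.95), CCL16 at 1.65 and 0.626 (−0.70) and CCL2 at 1.95 and 1.43 (−0.28). CCL15, CCL16 and CCL2 lie on chromosome 17, with read ratios of 0.386, 0.378 and 0.741, and may not be independent. Olfactory receptor rows lay higher (15 rows, 1 at least 2-fold lower, median 0.33, percentile 99.5), although 302 of 378 rows of this family were at 0 in both libraries. OR2AE1 had a log2 ratio of 0.72, against −1.08 for OR5AN1 and −0.85 for OR8G1. OR8B3, below the level filter and outside the list median, had 0.211 and 0.917 RPKM. Clustered protocadherin rows also lay higher (7 rows, none 2-fold apart, median 0.35, percentile 98.7). PCDHGC5 (0.57), PCDHGC4 (0.46) and PCDHGB5 (0.44) had positive ratios. PCDHGA4 (−0.47) was below the level filter and outside the list median. Genes of the gamma cluster share their last exons, so these values are not independent. Each of the 5 calls was lost under at least 1 alternative filter or pseudocount.

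The remaining 21 tested lists had medians inside the random range, with percentiles from 3.45 to 93.1. In the list of sirtuins and H3K9 methylation (10 rows, percentile 3.45), LMNB1, a lamin of the nuclear envelope, stood at 3.75 and 0.857 RPKM (−1.36), and CBX5, which encodes heterochromatin protein HP1 alpha, at 2.32 and 1.52 (−0.39). Mitosis rows (8 rows, percentile 3.48) included TPX2 at 0.79 and CDCA3 at −0.46. DNA replication rows (8 rows, percentile 7.28) included SLBP, the histone mRNA stem-loop binding protein gene, at 5.76 and 1.83 RPKM (−1.25). Core histone cluster rows (7 rows, percentile 76.7) included HIST1H4G at 0.80 and HIST2H2BC at −0.77. Unfolded protein and amino acid response rows (6 rows, percentile 33.8) included CANX at 0.86 and PHGDH at −1.07. Housekeeping rows (6 rows, percentile 53.9) ran from 0.79 for GAPDH to −0.37 for PPIA. Epithelial marker rows (6 rows, percentile 42.8) included CLDN7 at 0.74 and CDH1 at −0.29.

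A further 19 lists had fewer than 5 rows above the level filter and were not tested. Of p53 targets, 4 rows passed the filter, none 2-fold apart, with CCNG1 at −0.43 and DDB2 at 0.22. Of 3 rows of CDK inhibitors, CDKN1C was at least 2-fold higher and CDKN1B stood at −0.66. Of 4 heat shock rows, HSPB8 had 2.31 RPKM in the control and 7.17 with H1.5 siRNA. Interferon-stimulated rows (3 rows, none 2-fold apart) included SP110 at 0.67 and IFI6 at 0.37. RNA interference rows (3 rows) included TNRC6C at −0.48. The 3 endothelial marker rows lay between −0.13 for PLVAP and 0.07 for EGFL7, and blood, neural, pluripotency and smooth muscle markers had 1 row each above the filter.

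Gene families and clusters were also compared over all rows above 0 with a pseudocount of 0.1 RPKM. Of 12 families, 1 stood apart, where 0.6 would be expected by chance if rows were independent. Keratin and keratin-associated rows lay higher with H1.5 siRNA (75 rows, median log2 ratio 0.14, percentile 99.97), with 34 rows at 0.1 RPKM or more in each library. In the main comparison the same family did not stand apart (15 rows, median 0.14, percentile 88.4). KRT77 stood at 70.1 RPKM in the control and 97.7 with H1.5 siRNA, and KRT32 at 8.26 and 5.11 RPKM. On this wider set olfactory receptors had percentile 97.3 (76 rows), clustered protocadherins 16.2 (41 rows) and chemokine and interferon clusters 88.2 (24 rows), all inside the random range.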

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

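No paired analysis was possible because each group has 1 library, and no library could be left out. Counts of rows at least 2-fold apart followed the settings that act on low rows or on the threshold; the cause is the construction of the setting. Against 44 higher and 57 lower rows, a pseudocount of 0.1 RPKM gave 93 and 112, one of 5 RPKM gave 8 and 9, a mean of at least 5 RPKM gave 21 and 27, a threshold of 1.5-fold gave 197 and 192, and one of 3-fold gave 5 and 5. The other settings, among them a minimum of 20 estimated reads chosen after seeing the data, stayed within 1.5 times. The 3 scalings shifted ratios by −0.05 at most. The Pearson r of 0.951 became 0.981 with no filter, 0.922 at a mean of at least 5 RPKM and 0.939 with a pseudocount of 0.1 RPKM, and HIST1H1B gave no ratio under any setting. The count of lists standing apart fell from 5 to 1 at a mean of at least 5 RPKM, where 11 lists could be tested. It was 7 with no filter, where 43 could be tested, and 6 with a pseudocount of 5 RPKM. With no filter, chemokine and interferon clusters moved to percentile 85.2 and clustered protocadherins to 25.1, on the opposite side; the cause was not tested. Over the 26 lists tested in the main comparison and all settings, 6 of 270 percentiles moved inside the bounds, these 2 included. A further 5 moved outside, and 259 stayed inside or outside. Cancer-testis genes stayed inside but went from 91.6 to 3.46 with no filter.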

Other observations

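Apart from the exact test of reads, the tests in this part were chosen only after the values had been seen. Where both parts of a chromosome window gave the same displacement, row values could be read against the genes lying there, as a hypothesis. Under the main setting, some genes lay under 2 rows with no shared exon. The following are among those with the highest and the lowest mean log2 ratio. They were taken only from genes whose 2 rows had ratios of the same sign, so the agreement of the named pairs is partly built in. ITPR3, an inositol trisphosphate receptor gene, lies under MLN with log2 ratio 1.37 and LEMD2 with 1.31. BRPF3, a bromodomain protein gene, lies under C6orf222 (1.15) and PNPLA1 (0.81), and DBN1, which encodes the actin-binding protein drebrin, under PFN3 (0.75) and F12 (0.74). In the other direction, ABCF1 lies under PPP1R18 (−0.55) and NRM (−0.53), and GMPPA under ABCB6 (−0.49) and ZFAND2B (−0.57). The correlations used genes under 2 such rows whatever the signs, but only rows lying over 1 gene. These rows needed a mean of at least 1 RPKM and at least 100 estimated reads. For each gene, the highest row was paired with the next highest that shared no exon with it. Low rows over a gene with a high row were thus left out, although they could have gone against the reading. Over the 21 genes of the main setting, the log2 ratios of the pair gave a Pearson r of 0.958 and a Spearman rho of 0.896. Without the 2 genes farthest from the median, r was 0.917. Over 51 genes in windows that agreed under any setting, r was 0.765 and rho 0.705, and r without the 2 farthest was 0.665. Each r and rho over all genes of a set had a permutation p of 1e-05, two-sided, the smallest that 100000 permutations can give; genes are not independent replicates. Neighbouring rows within 100 kb that lie over different genes gave an r of −0.00138 (111 pairs). No row lay over HIST1H1B, HIST1H1A, HIST1H1C, HIST1H1D or HIST1H1E when displaced, so the knockdown cannot be checked in this way.

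The pattern to be explained is that rows of abundant fibroblast genes stood at or near 0 beside high rows of genes such as LINGO4. A candidate explanation is that reads lie at positions displaced from the gene models, as would happen if reads were placed on one genome build and counted on gene models of another. Both parts of a window, made of alternate blocks, picked displacements within 1 kb in 7 of 54 windows, against 0.0185 expected by chance and at most 1 in each of 20 random reassignments of the values; the other settings gave 5 or 6, and 0 in each reassignment. Displacements in the 7 windows ran from −108 kb on chromosome 6 to 292 kb on chromosome 2. Windows that agreed only under another setting reached farther, to −1483 kb on chromosome 3 and 557 kb on chromosome 20. Over windows that agreed under any setting, 85.2% of 743 rows with a mean of at least 1 RPKM then lay over a coding exon, against 12.7% of 1515 rows at 0; turned the other way, these were 50.1% and 28.4%, and part of the gap is built in, since displacements were picked by overlap. Of 16 abundant genes under a displaced row, 5 were still higher in the row of their own name and 6 displaced rows were below 1 RPKM (median of the displaced rows 3.19, of the own rows 0.0261), a comparison with the same built-in gap.

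For other explanations that were examined, the values argue against them. Had reads with several matches been dropped, genes without a named pseudogene should mostly keep their level, but 77.4% of 84 such genes had a mean below 1 RPKM. This does not exclude it for each gene. Similar genes other than named pseudogenes were not considered, and the lists were not limited to genes known to be active in fibroblasts. Had values slipped by a fixed number of rows, some lag would restore the abundant genes, but over lags up to 200 rows either way their highest median was 0.0156 RPKM. Whether genome builds were combined, and which, was not tested, since no annotation of an earlier build was used here. Most windows gave no reproducible displacement, so the reading extends to 9 chromosomes only. It does not reach the high rows LINGO4, MIR589, GRINA, CA9 and HOXC8, whose chromosomes had no such window, and their levels stay unexplained. No biological explanation was tested for this pattern.

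The second pattern is the 101 rows at least 2-fold apart. Counting noise of few reads is an unlikely source, since 100% of the 100 rows with a read estimate passed the exact test of reads. Whether these differences come from the H1.5 siRNA or from culture, transfection or library preparation cannot be told apart with 1 library per group.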
